A study of Mus musculus with 2 samples.

How the data were processed

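Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used by the authors to map H3K4me1, the monomethylated form of lysine 4 of histone H3, in the hindbrain of mouse embryos of the B6NCrl strain at embryonic day 16.5. H3K4me1 marks active and poised enhancers and the flanks of promoters. Per the labels, there were 2 biological replicates of 1 group, each a pool of embryos of both sexes. Replicate 2 was pooled from 37 embryos, and the number behind replicate 1 is not given in the sources used here. Both libraries name the same strain and tissue, so the comparison that the design implies is between the replicates, and no comparison between groups was possible. No paired analysis was possible because there is only 1 group.

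The deposited files used here are 4 peak lists on the mouse build mm10, per the file headers and the labels. The first was called on replicate 1, the second on replicate 2, and the third, called the pooled list here, on both replicates together. The fourth, called the replicated list here, was derived by the authors from the other 3 and proved to be a subset of the pooled list. Each peak has a fold enrichment over its control, a ratio set by the authors' peak caller and deposited with the list. Each peak also has the deposited −log10 p and −log10 q of the authors' peak caller. The deposited display score and the offset of the summit were not used for any result. The aligner, the peak caller and its threshold are not given in the sources used here. The lowest −log10 p was 2.02 in replicate 1 and 2.00 in replicate 2. Per the file headers, the lists of replicate 1 and of the pooled replicates were derived from 1 file more than that of replicate 2, and the role of that file is not stated. Values of the pooled and replicated lists are the authors' values and have no SD.

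The files give no read counts, so the sequencing depth of each library is unknown and no interval or floor that needs it is given. Depth and the quality of the immunoprecipitation set how many peaks a caller can find, so numbers of peaks and covered bases were also compared at equal numbers of peaks. For that, the strongest replicate 1 peaks by −log10 p were taken, as many as replicate 2 has. Fold enrichment and −log10 p were used only to describe, rank or filter peaks within a list, apart from a rank correlation of matched peaks.

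Peaks on chromosomes 1 to 19 and X were analysed. Sequence and repeat masking came from the GRCm38.p6 assembly, which is the same build as mm10, and gene models from GENCODE mouse release 21, with 21755 protein-coding genes and 41135 transcription start sites (TSS) of protein-coding transcripts. Chromosome lengths of the assembly were compared with the peaks before use. A peak was shared when at least 50% of its length lay in peaks of the other list. Overlaps by chance came from 1000 rotations of a list, in which all peaks of a chromosome are moved by the same random offset. A peak's class was set by its centre, taken in the order promoter (within 1 kb of a TSS), exon, intron and intergenic.

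The profile around TSS, the windows of genes, their matching, bins of the genome and the distances from peaks to genes used 1 TSS per gene, the 5′ end of its annotation, and promoters used the starts of all protein-coding transcripts. Peak coverage of a gene was the percent of the window of 50 kb on each side of its TSS that lies in peaks. A window of this size also holds neighbouring genes and their peaks. The 25 gene lists were fixed before the data were examined. They hold 297 entries picked by symbol (Ttr stands in both the choroid plexus and the liver list), all found in the annotation, and the olfactory and vomeronasal receptors, picked by the pattern of their names. The median of a list was placed among the medians of 10000 random lists of equal size matched on the number of protein-coding TSS in the window. A list was called above or below only if its median lay among the top or the bottom 2.5% of random lists in the replicated list and in both replicates. Genes and peaks are not replicates, so these percentiles describe these libraries and no p-value is given. Values of single genes and lists are those of the replicated list unless a replicate is named. Values of each replicate are given for some of them, with the mean and SD over n = 2 replicates in a few cases. Where they are not given, the replicates can still differ widely, as for Meis1 at 11.6% in replicate 1 and 2.68% in replicate 2. An SD over 2 libraries is itself uncertain.

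The genes named in the text were chosen by a rule set beforehand. From each list it takes the 3 genes with the highest and the gene with the lowest percent of the window covered by replicated peaks. It also takes the genes at or nearest to the 10 replicated peaks with the highest fold enrichment, the genes overlapping the 10 longest stretches (replicated peaks at most 1 kb apart, joined), and every Hox gene. A few genes that this rule takes are not reported here. A few other genes are named in the closing observations, where it is said that they were chosen after their values were seen.

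The list call and the overlap were tested on simulated data. Among 200 random lists with no added coverage, 0% of lists of 10 genes were called above and 2.0% below, and of lists of 15 genes 1.0% above and 1.5% below. With coverage raised 2-fold in the gene list comparison, 33.5% of lists of 10 genes and 32.0% of lists of 15 genes were called above, and with coverage raised 3-fold 52.0% and 61.5%. A list that was not called can therefore still differ by such an amount. In the simulated replicate overlap of 146051 peaks, 30% planted overlap gave an excess of 29.6% over rotations.

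The alternatives tried were other overlap rules, stricter peaks (−log10 q of at least 3, or a fold of at least 3), equal numbers of peaks, other promoter and window sizes, other backgrounds, the pooled list, leaving out each replicate, other joining distances and, chosen after the data were seen, 3 further ones for the gene lists and 1 for the classes of peaks. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Left out were peaks outside the 20 chromosomes named, which are listed in the closing section.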

Results

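H3K4me1 was mapped in embryonic day 16.5 mouse hindbrain, the tissue that forms the cerebellum, pons and medulla, in 2 replicates of 1 group. Replicate 1 held 146051 peaks that covered 61.0 Mb, or 2.38% of the known sequence of the analysed chromosomes, and replicate 2 held 65456 peaks that covered 24.8 Mb, or 0.968%. The pooled list held 112366 peaks over 54.5 Mb and the replicated list 81198 peaks over 46.9 Mb. Replicate 1 thus had 2.23 times as many peaks and 2.46 times as many covered bases as replicate 2. The number of reads behind each list is unknown. Since the median coverage of gene windows was 3.11% in replicate 1 and 1.22% in replicate 2, each gene list was read against random lists within each replicate.

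Which genes carried the mark was read from the windows around their TSS. Genes that pattern the early hindbrain stood above matched random genes. The 12 patterning transcription factors had a median of 4.93% of the window covered by replicated peaks, against 1.45% for random lists (percentile 99.9, and percentiles 99.8 and 99.6 in replicates 1 and 2). All 12 were above the median of all protein-coding genes, 2.43%. Their own medians were 5.61% in replicate 1 and 2.23% in replicate 2 (mean 3.92% ± 2.39, SD, n = 2). Gbx2, a factor of the midbrain-hindbrain boundary, was covered at 8.21%, and Pax2, active at the same boundary, at 7.38%. The lowest was Irx2 at 2.54%.

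Progenitor and radial glia genes were also above random lists, with a median of 3.86% against 1.55% over 14 genes (percentile 99.2, and 99.9 and 98.1 in replicates 1 and 2). Notch1, the receptor that keeps neural progenitors undifferentiated, had 26.3% of its window covered, which ranked it 31 of all protein-coding genes (26.1% in replicate 1 and 15.1% in replicate 2, mean 20.6% ± 7.77, SD, n = 2). Its gene lies on the minus strand of chromosome 2, from 26457903 to 26516663. Nes, which encodes the intermediate filament nestin, was covered at 17.8% and Hes5, a Notch target, at 9.93%. Ptprz1 was the lowest at 0.510%. When the random genes were matched on GC content in place of TSS number, the patterning list fell to percentile 84.0 and the progenitor list to percentile 77.1 in the replicated list, and neither was called. Both calls also ended with no matching (percentiles 95.2 and 86.6), and with peaks of −log10 q of at least 3 alone, of which replicate 2 held only 6443.

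The housekeeping list had the highest median, 8.27% over 15 genes (9.03% in replicate 1 and 5.05% in replicate 2, mean 7.04% ± 2.81, SD, n = 2), and was above random lists in all 3 lists (percentiles 99.8, 99.8 and 99.9). It held under GC matching (percentile 99.1) and was lost with windows of 100 kb. The elongation factor gene Eef2 was covered at 14.8%, the ribosomal protein gene Rps18 at 13.97% and Polr2a, the large subunit of RNA polymerase II, at 11.03%. Hprt, on chromosome X, had no replicated peak in its window. The pan-neuronal genes came next, with a median of 5.20% over 15 genes against 1.71% for random lists, but were not called, since percentiles of 99.92 and 99.95 in the replicated list and replicate 1 stood beside 96.5 in replicate 2. With GC matching the list was above in all 3 (percentile 98.9 in replicate 2). Rbfox3, which encodes the neuronal splicing factor NeuN, was covered at 16.5%, Elavl3 at 9.35%, the adhesion molecule gene Ncam1 at 8.25% and Elavl4 at 0.239%.

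None of the lists of hindbrain neuron types was called. The rhombic lip and granule cell list had a median of 3.21% over 15 genes (percentile 95.7), with Nhlh1 at 16.4%, Meis1 at 9.33%, the axonal adhesion gene Cntn2 at 8.60% and Etv1 at 0.789%. The Purkinje and cerebellar GABAergic list had 3.36% over 15 genes (percentiles 97.49, 81.7 and 97.1 in the replicated list, replicate 1 and replicate 2), with Foxp4 at 12.3%, Lhx1 at 6.73% and Car8, a Purkinje cell marker, at 0.192%. Brainstem neuron transcription factors had 2.49% (percentile 86.6), with Lmx1b at 8.37%, Phox2a at 5.22%, Gata2 at 4.29% and the motor neuron gene Isl1 at 0.478%. The serotonin and noradrenaline list had 1.49% against 1.62% for random lists (percentile 43.5). Within it Fev, the transcription factor of serotonergic neurons, was covered at 7.34%, Ddc at 3.6% and Th, the rate-limiting enzyme of catecholamine synthesis, at 3.29%, while Maob, on chromosome X, had no peak. Matched on GC content, the percentiles in the replicated list were 90.6 for rhombic lip, 88.2 for Purkinje, 8.5 for brainstem and 10.2 for serotonin lists.

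Among glial and synaptic genes, the astrocyte list had a median of 4.59% (percentiles 96.6, 98.8 and 84.6 in the replicated list, replicate 1 and replicate 2). Nfix, a nuclear factor I gene of glial differentiation, was covered at 22.7%, Gfap at 7.84%, the glutamate transporter gene Slc1a2 at 6.38% and Gja1 at 0.761%. The oligodendrocyte lineage list had 4.17% (percentile 95.7), with Cspg4 at 7.57%, Olig1 at 6.66% and its neighbour Olig2 at 6.15%. The neurotransmission list had 2.65% (percentile 79.9), with the NMDA receptor gene Grin1 at 12.2% and the vesicular transporter genes Slc17a7 at 9.61% and Slc32a1 at 6.65%. With GC matching the percentiles in the replicated list were 90.2 for the astrocyte, 23.1 for the oligodendrocyte and 58.4 for the neurotransmission list.

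Lists of other regions, cell types and tissues were not called either. The forebrain transcription factors had a median of 2.54% over 19 genes (percentile 86.3), with Lhx6 at 6.42%, Eomes at 6.08%, Emx1 at 4.46% and Six6 at 0.305%. Of the cell types that a dissected hindbrain can also hold, the erythroid list had 4.51% (percentile 80.02), the microglia and myeloid list 4.07% (percentile 76.3), the meninges and fibroblast list 2.66% (percentile 79.1), the choroid plexus list 2.55% (percentile 82.6) and the endothelial list 1.77% (percentile 53.8). The highest genes of these lists were Fcer1g at 11.8%, C1qa at 7.14%, Aif1 at 6.51%, Epor at 11.2%, Slc4a1 at 9.83%, Klf1 at 9.58%, Pdgfrb at 7.39%, Foxc2 at 6.53%, Col1a1 at 4.21%, Foxj1 at 6.79%, Folr1 at 6.09%, Msx1 at 5.31%, Pecam1 at 4.60%, Flt1 at 4.08% and Sox17 at 2.5%. The lowest members, Itgam, Alas2, Lum, Kcnj13 and Tek, had no replicated peak in their windows. With GC matching the forebrain list stood at percentile 64.1 in the replicated list. The erythroid list then stood at 80.3, microglia and myeloid at 22.1, meninges and fibroblast at 90.3, and choroid plexus and endothelium at 13.6 each.

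Of the tissues outside the brain, skeletal muscle had a median of 3.67% (percentile 89.3), heart 2.98% (percentile 76.9), epithelium 1.62% (percentile 28.4), liver 1.58% (percentile 9.63) and germline and pluripotency genes 1.33% (percentile 20.7). The muscle regulator Myod1 was covered at 10.1%, Tnnt3 at 7.17% and Ckm at 5.54%, the heart genes Nppa at 5.49%, Tnni3 at 5.4% and Myh6 at 5.34%, and the liver genes Apoa2 at 10.04% and Nr1i3 at 8.71%. Apoa2 and Nr1i3 lie close to Fcer1g of the microglia and myeloid list, and their windows share the same strongest replicated peak. Epcam stood at 4.25%, Grhl2 at 3.38%, Vil1 at 3.17%, Nanos2 at 14.8%, Mael at 6.82% and Nanog at 2.19%. Actn2 was covered at 0.306%, and Myf5, Afp, Cdx2 and Dazl had no replicated peak. The epithelial list was below random lists when these were matched on GC content (percentile 0.900). With the same matching skeletal muscle stood at percentile 20.0 in the replicated list, heart at 10.4, liver at 3.62 and germline genes at 9.69.

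The receptors of smell and pheromones were the list called below. Of 1466 olfactory and vomeronasal receptor genes, 1317 had no replicated peak in the window, 1285 had none in replicate 1 and 1357 none in replicate 2, and the median was 0 in each list against 3.27% for random lists in the replicated list. The exceptions Olfr221 at 12.1%, Olfr370 at 5.84% and Olfr1513 at 5.65% were the highest, and Olfr1 had no peak. Matched on GC content, the random lists also had a median of 0, so that background could not place this list. With peaks of −log10 q of at least 3 alone, the list was not called either, although its percentile was 0 in the replicated list.

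**Figure D1:**
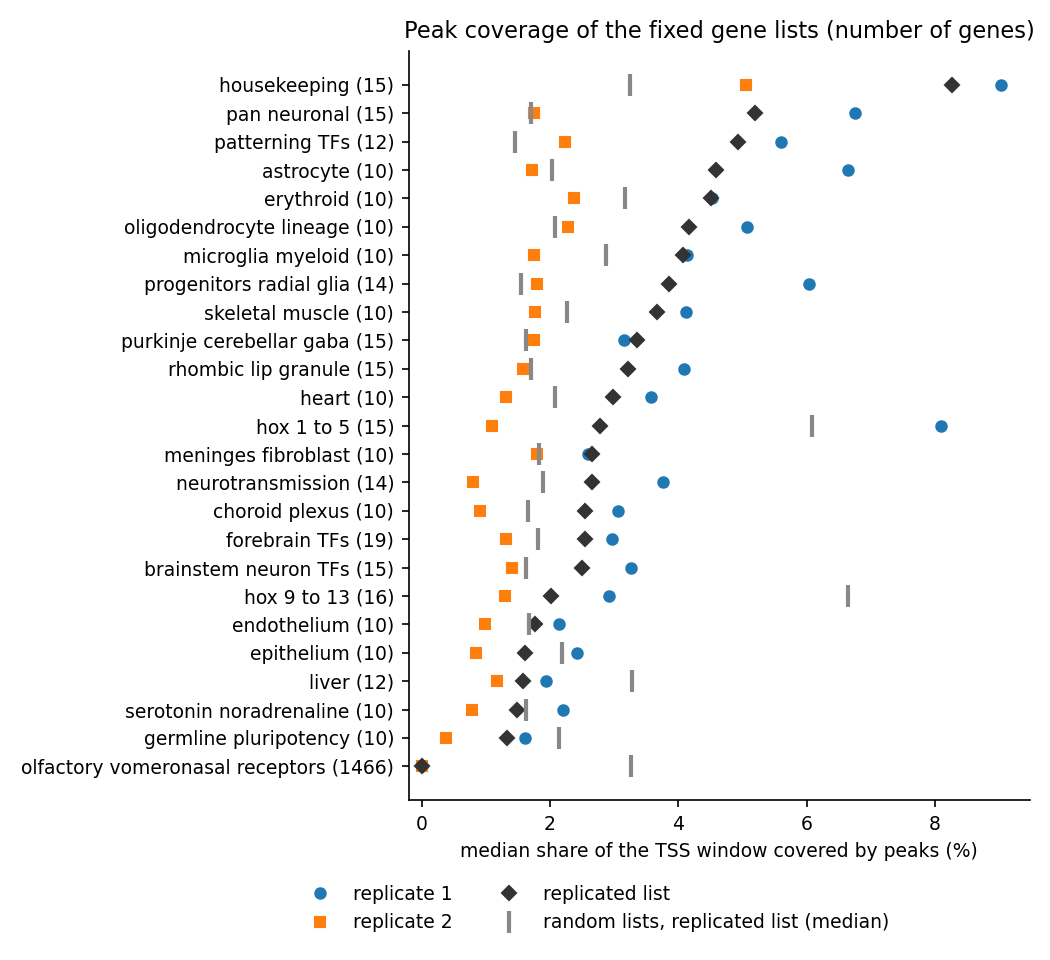
The median share of the TSS window covered by peaks, in percent on the horizontal axis, for each fixed gene list on the vertical axis, with the number of genes in brackets; circles are replicate 1, squares replicate 2, diamonds the replicated list and grey bars the median of TSS-matched random lists in the replicated list. Housekeeping genes reached 8.27%, patterning factors 4.93% and olfactory and vomeronasal receptors 0% in the replicated list.

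The Hox genes give the axial address of hindbrain and spinal cord, and paralog groups 1 to 5 are those that the hindbrain expresses. Peaks on Hox genes did not follow that order in both replicates. Over the gene body and 2 kb on each side, groups 1 to 5 had a mean of 8.33% covered in replicate 1 and 1.30% in replicate 2 (mean 4.81% ± 4.97, SD, n = 2), groups 6 to 8 had 5.01% and 1.957% (3.48% ± 2.16, SD, n = 2), and groups 9 to 13 had 4.46% and 3.41% (3.93% ± 0.747, SD, n = 2). The anterior groups were thus the highest in replicate 1 and the lowest in replicate 2. In the replicated list the 3 means were 3.92%, 3.19% and 4.62%, and over gene bodies alone 3.46%, 5.92% and 6.39%.

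Hoxb2 and Hoxb3, on chromosome 11, had 22.7% and 20.5% covered in replicate 1 but 0% and 2.16% in replicate 2, and 16.6% and 11.4% in the replicated list. Hoxd1, on chromosome 2, was the highest Hox gene of the replicated list at 23.1% (19.6% and 9.53% in replicates 1 and 2). Of the posterior genes of the same cluster, Hoxd9 (12.3% and 13.5%), Hoxd11 (10.3% and 8.34%) and Hoxd13 (8.97% and 9.15%) were covered in both replicates. So was Hoxd8, at 12.1% and 11.1%. Hoxd10 (6.89%) and Hoxd12 (2.21%) were covered in replicate 1 but not in replicate 2. Hoxd3 had 3.18%, Hoxd12 2.76% and Hoxd4 1.959% in the replicated list, and Hoxd10 had 0%. In the Hoxa cluster the replicated list covered Hoxa13 at 11.8%, Hoxa7 at 5.61%, Hoxa9 at 5.31%, Hoxa11 at 4.18%, Hoxa10 at 2.36% and Hoxa3 at 0.613%, and Hoxa2, Hoxa4, Hoxa5 and Hoxa6 at 0%, although replicate 1 covered Hoxa4 at 9.55%. Hoxb9 was at 4.42%, Hoxb8 at 4.12% and Hoxb7 at 0.0660%. Hoxb1, Hoxb4, Hoxb5 and Hoxb6 had no peak in either replicate, and Hoxb13 one in replicate 1 alone. The Hoxc cluster was the least covered, with a mean of 1.01% in the replicated list against 9.18% for Hoxd, 3.66% for Hoxb and 2.72% for Hoxa. Its values were 2.61% for Hoxc6, 2.27% for Hoxc13, 2.25% for Hoxc9, 1.94% for Hoxc5 and 0% for Hoxc4, Hoxc8, Hoxc10, Hoxc11 and Hoxc12.

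By TSS windows, the posterior Hox list had a median of 2.01% against 6.65% for random lists, at percentiles 1.47, 1.81 and 2.83 in the replicated list and replicates 1 and 2, so that it was not called below. Without replicate 2 it was called below, but that call rests on the 1.81 of replicate 1 alone and adds nothing to it. The list was also called below with GC matching (percentiles 0, 0.0200 and 0.0900) and, in a setting chosen after the data were seen, without chromosome X. Members with overlapping windows counted as 1, also chosen after the data were seen, moved it the other way, to percentile 12.9 in the replicated list. The anterior list had 2.78% (percentile 5.81), but 8.09% in replicate 1 against 1.09% in replicate 2. At equal numbers of peaks replicate 1 had 2.22%, 2.03 times the replicate 2 value, against 1.63 times for all genes. In the replicated list, the TSS windows of Hoxd4 were covered at 5.88% and those of Hoxd3 and Hoxb1 at 5.87%. Those of Hoxd9 were at 6.08%, Hoxd10 and Hoxd11 at 5.21% and Hoxb13 at 0.363%. Members of each list lie in only 4 clusters and share windows, and the annotated bodies of Hoxa3, Hoxc5, Hoxd3 and Hoxd4 overlap neighbouring Hox genes.

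**Figure D2:**
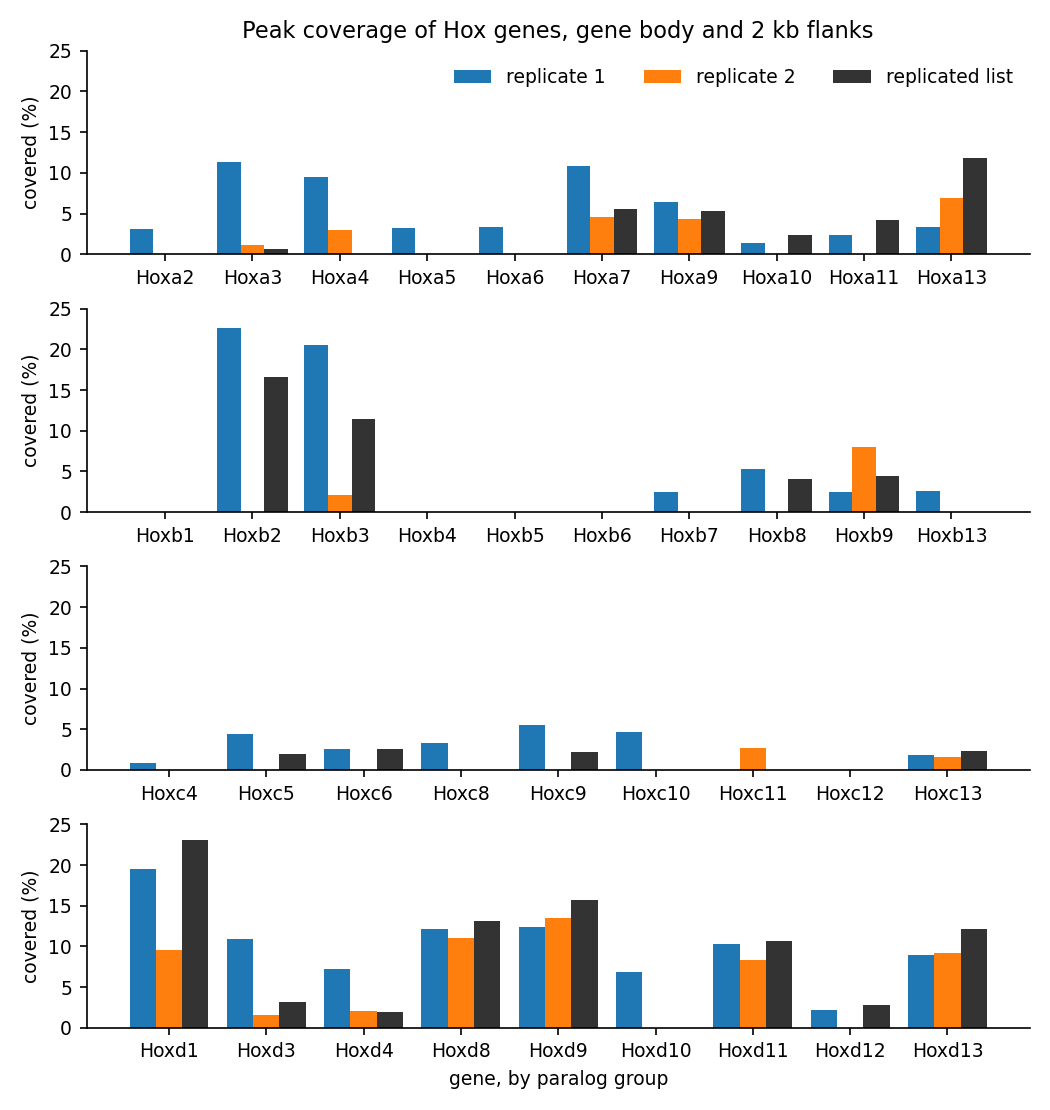
The percent of each Hox gene shown, with 2 kb on each side, covered by peaks on the vertical axis, in panels for the Hoxa, Hoxb, Hoxc and Hoxd clusters with genes ordered by paralog group on the horizontal axis; bars are replicate 1, replicate 2 and the replicated list. Hoxb2 and Hoxb3 reached 22.7% and 20.5% in replicate 1 and 0% and 2.16% in replicate 2, while Hoxd9 stood at 12.3% and 13.5%.

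Around the TSS of protein-coding genes, 1 per gene, the mark flanked the start and was thinner on it. Replicated peaks covered 8.65% of TSS, 17.2% of the positions 600 bp upstream and 28.7% of the positions 1100 bp downstream, 3.32 times the share at the TSS. In replicate 1 the same shares were 8.90% at the TSS, 20.4% at the upstream and 30.2% at the downstream maximum, and in replicate 2 they were 4.99%, 8.88% and 18.1%. The dip on the start and the higher downstream shoulder were thus present in each replicate, and the downstream maximum lay 1100 bp from the TSS in replicate 1 and 1200 bp in replicate 2.

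**Figure D3:**
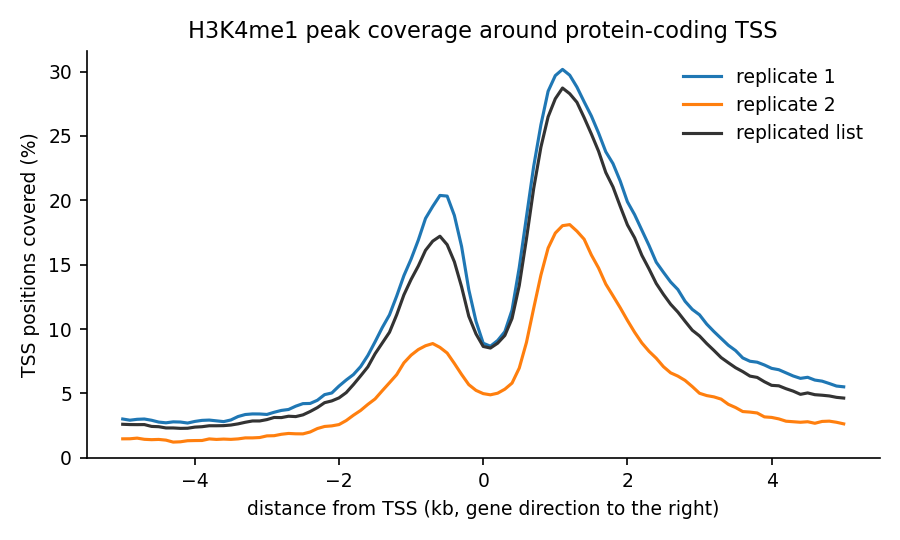
The percent of protein-coding genes with a peak at each distance from the TSS, from 5 kb upstream to 5 kb downstream in the direction of the gene, for replicate 1, replicate 2 and the replicated list. All 3 curves dip near the TSS and reach their maximum downstream, at 30.2%, 18.1% and 28.7%.

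The strongest peaks mostly lay just downstream of the 5′ end of a gene. The 10 replicated peaks with the highest fold enrichment over control had the authors' values from 12.1 to 10.4. The first covered 1692 bp of chromosome 10, from 81494140 to 81495831, in an intron of Ncln, which encodes a membrane protein of the endoplasmic reticulum, 1.41 kb downstream of its 5′ end. Next came Mrpl28, a mitochondrial ribosomal protein gene (11.5, in an exon), Hdgfl2 (11.5), the elongation factor gene Eef1d (11.4), Trim11 (11.2), a peak shared by Adam1a, Gm42878 and Mapkapk5 (11.1), Mapk1ip1 (11.1, upstream of Ppp2r2d), the signal recognition particle gene Srp68 (10.8), Dpp9 (10.4) and Wdr24 (10.4). Each of the 10 was found in both replicates, with folds of 10.6 to 13.4 in replicate 1 and 6.20 to 10.03 in replicate 2. Measured from the 5′ end of the nearest protein-coding gene, the centres of 9 lay 1.06 to 1.88 kb downstream, and that of the peak in Mapk1ip1 lay 1.94 kb upstream of Ppp2r2d. The centre of the peak at Adam1a lay within 1 kb of the start of a protein-coding transcript.

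Genome-wide, 16.3% of replicated peaks (13258) had their centre within 1 kb of a TSS, against 2.21% for rotated peaks, 7.39 times as many. Exons held 3.76% (1.46 times the rotated share) and introns 54.2% (1.44 times), and intergenic sequence held 25.7%, or 0.447 times the rotated share. Promoters held 12.6% of peaks in replicate 1 and 17.0% in replicate 2 (mean 14.8% ± 3.09, SD, n = 2). All 4 observed shares lay outside the range of the 1000 rotations, which for promoters ran from 1.94% to 2.57%.

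The longest stretches of the mark mostly lay on protein-coding genes, 9 of the first 10. Joined at gaps of up to 1 kb, replicated peaks formed 53123 stretches with a median of 668 bp, of which 683 were at least 5 kb and 70 at least 10 kb long. The longest ran for 28.9 kb on chromosome 14, from 25461271 to 25490181, within Zmiz1, a transcriptional coactivator gene, and was covered by peaks for 80.2% of its length in replicate 1 and 59.9% in replicate 2. It was followed by stretches on the kinase gene Map4k4 (25.9 kb), Notch1 (22.2 kb), Mtss1 (19.9 kb), Cxxc5 (19.2 kb), the reelin receptor gene Lrp8 (19.14 kb), Gse1 with the overlapping model Gm20388 (17.9 kb), the chromatin reader gene Zmynd8 (17.7 kb) and Ahdc1 (16.5 kb). A stretch of 17.1 kb on chromosome 7, from 79510812 to 79527897, overlapped no protein-coding gene, the nearest being Polg at 44.4 kb, but overlapped Mir9-3hg, the host transcript of a copy of the neural microRNA miR-9. Over the 10 stretches, 70.9% to 92.8% of the bases were covered in replicate 1 and 34.3% to 83.7% in replicate 2. Which stretches are longest depends on the joining distance, since 5 of the 10 stayed among the longest 10 at 3 kb and 2 without joining.

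Chromosome X carried far less peak coverage than any autosome. Replicated peaks covered 0.131% of it, against 1.22% for chromosome 3, the lowest autosome, and 3.33% for chromosome 11, the highest. Relative to the autosomes together, coverage of X was 0.0913 in replicate 1 and 0.0326 in replicate 2 (mean 0.0619 ± 0.0415, SD, n = 2), and 14.5-fold lower in the replicated list. Against autosomal bins of 100 kb matched on GC content, repeats and TSS number, it was 4.28-fold lower in the replicated list. The X-linked list genes Maob and Hprt were the lowest of their lists, and Alas2 was 1 of 2 erythroid genes without a replicated peak. Replicate 1 had 1227 peaks on X and replicate 2 had 196.

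**Figure D4:**
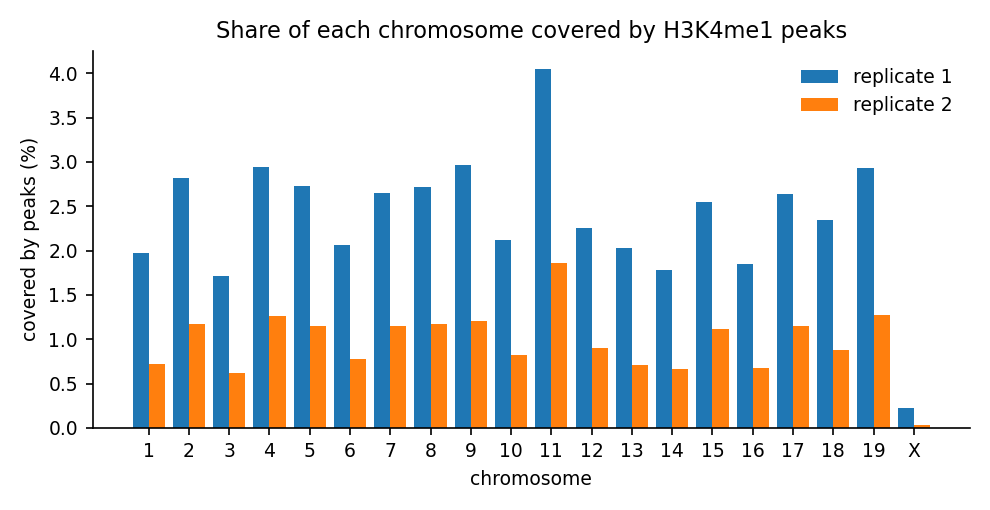
The percent of each chromosome covered by peaks, on the vertical axis from 0, for chromosomes 1 to 19 and X on the horizontal axis, with bars for replicate 1 and replicate 2. Chromosome 11 is the highest at 4.05% and 1.86%, and X the lowest at 0.225% and 0.0327%.

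Most replicate 2 peaks lay in replicate 1 peaks, while most replicate 1 peaks had no counterpart in replicate 2. Of the replicate 2 peaks, 51631 (78.9%) had at least 50% of their length in replicate 1 peaks, against 2.61% after rotation, and of the replicate 1 peaks 34339 (23.5%) lay in replicate 2, against 1.01%. The 19.7 Mb covered in both made up 32.3% of the replicate 1 bases and 79.6% of the replicate 2 bases, and 29.8% of the bases covered in either. At equal numbers of peaks the shares were 38.4% of replicate 1 and 62.2% of replicate 2. Recovery rose with strength, from 8.98% to 67.8% between the weakest and the strongest of 10 equal groups of replicate 1 peaks by −log10 p. Across 33630 peaks matched one to one, the authors' fold enrichments of the replicates had a Spearman's rho of 0.336, which describes peaks within these libraries. Over all protein-coding genes the window coverages of the replicates had a rho of 0.954, again across genes that are not independent.

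**Figure D5:**
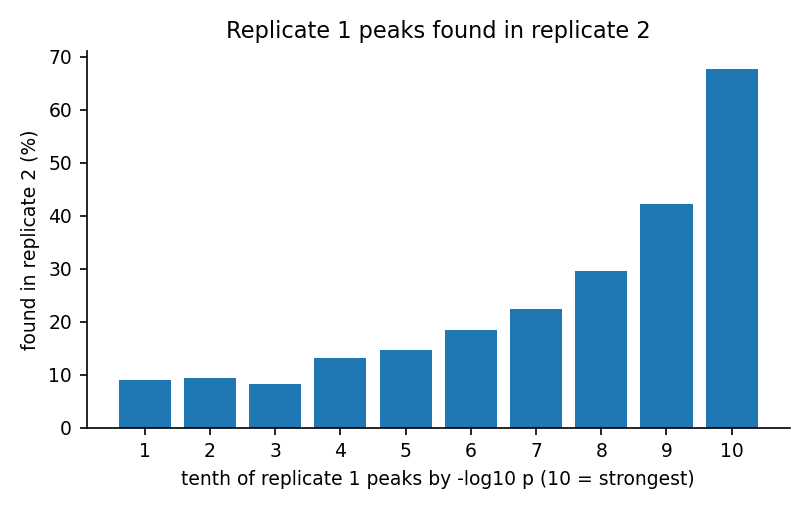
The percent of replicate 1 peaks with at least 50% of their length in replicate 2 peaks, on the vertical axis from 0, in 10 equal groups of replicate 1 peaks by −log10 p on the horizontal axis, with the strongest at 10. The share is 8.98% in the weakest group and 67.8% in the strongest.

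Peaks in 1 replicate only were weaker and less often at promoters. Of replicate 1, 94425 peaks (64.7%) touched no replicate 2 peak, and 9.50% of these were promoter peaks against 18.3% of those that touched one. Of replicate 2, 8747 peaks (13.4%) touched no replicate 1 peak, with 10.8% against 17.9% at promoters. Median folds were 3.31 against 4.23 in replicate 1 and 3.23 against 3.57 in replicate 2. At equal numbers, 43.4% of replicate 1 and 32.3% of replicate 2 touched no peak of the other. The replicate 1 peaks alone covered a median of 5.95% of the windows of anterior Hox genes and 3.11% of those of pan-neuronal genes, against 1.21% over all protein-coding genes. At equal numbers of peaks, the median coverage of replicate 1 over that of replicate 2 was 2.03 for anterior Hox and 2.18 for pan-neuronal genes, below germline (2.53) and neurotransmission genes (2.52), against 1.63 over all genes.

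The replicated list kept 72.3% of the pooled peaks, and the kept peaks were wider (median 437 bp against 221 bp) and stronger (median fold 3.64 against 2.88) than those left out. Of the replicated peaks, 46647 (57.4%) touched a deposited peak of both replicates, 28974 (35.7%) touched replicate 1 alone, 2662 (3.28%) replicate 2 alone and 2915 (3.59%) neither. The list therefore holds peaks that a plain overlap with both deposited replicate lists would leave out. Keeping only those that touch both replicates left the same 4 gene lists called, a setting chosen after the data were seen.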

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

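Of the tests in this part, that of peak numbers for the neural genes, and the comparison of their peak strengths with random lists, were chosen only after the result was seen. The design has 1 group, so no biological explanation was tested for any pattern here.

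Peaks outside the analysed chromosomes were flagged as data that no comparison used. Replicate 1 had 4 such peaks among 146055, past a fixed limit of 3, with 2 on chromosome Y and 2 on an unlocalized sequence of chromosome X. That limit is no test of whether so few called peaks are signal. The pooled list had 2 and the replicated list 1, all on that X sequence, and replicate 2 had 0.

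Chromosome X carried less peak coverage than the autosomes. Sequence and gene content are argued against as the whole cause only as far as bins were matched on them. Replicated peaks covered 0.233 times the bases found in autosomal bins of 100 kb matched on GC, repeats and TSS number (95% bootstrap interval 0.170 to 0.287). The matched ratio was 0.286 in replicate 1 and 0.121 in replicate 2. Without matching, the ratio over these bins was 0.0714 in the replicated list, so matching narrowed the gap. The matching used broad groups of GC and of repeats, so differences within a group could remain and lower the matched ratio. A lower X signal against the peak threshold may add to it: replicate 1 had 249 X peaks with a fold of at least 4 (95% counting interval 219 to 282), between the 29.3 that matched autosomal bins give if the signal is lowered to 50% and the 329 at 75%. Replicate 2 had 23 (14.6 to 34.5), between 1.03 and 59.8. The range is wide, so this test is weak, and the explanation stays open.

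By covered bases, neural gene windows together kept less of replicate 1 in replicate 2: over 63 genes of the 5 neural lists, the median log2 ratio of replicate 1 to replicate 2 coverage was 1.43, against 1.07 for TSS-matched random lists. This was not shared by every neural list or limited to them, since at equal numbers the medians of replicate 1 over replicate 2 gave 1.20 for the oligodendrocyte list, 2.52 for neurotransmission, 2.53 for germline, 2.23 for choroid plexus and 1.63 for all genes. The lower number of peaks in replicate 2 is argued against as the whole cause. At equal numbers the median log2 ratio over the 63 genes was still 0.69 against 0.39 (percentile 99.5). The replicate 1 peaks then still covered 38.2 Mb against 24.8 Mb in replicate 2, so a difference in depth was not removed. GC-dependent recovery is argued against by percentile 99.98 among GC-matched lists. Weaker peaks stay open: replicate 1 peaks in neural windows were found in replicate 2 1.00 times as often as other peaks of equal strength, width and GC (95% bootstrap interval 0.843 to 1.10), and their mean −log10 p was 6.01 against 6.50 for TSS-matched lists (percentile 0.700). They were found more often than all other peaks (25.9% against 23.5%) and had no lower median fold (3.59 against 3.55), but with peaks counted for each gene window the share found was 25.6% against 28.7% for TSS-matched (percentile 10.7) and 34.2% for GC-matched lists (percentile 0), and found over expected was at percentiles 12.9 and 2.44.

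Peak coverage rose with GC content, with a Spearman's rho of 0.731 over 23868 autosomal bins of 100 kb. The number of genes in GC-rich sequence is argued against as the whole cause, since rho was 0.527 over 3289 bins without an annotated gene (95% bootstrap interval 0.490 to 0.562). GC-dependent recovery in the assay alone could not be decided. In the 20% of bins with the highest GC content, those with a protein-coding TSS had 2.41 times the coverage of gene-free ones (interval 1.93 to 3.09). The values were 6.11% against 2.53%, the latter from 99 gene-free bins. These bins were not matched on GC within that range, so a difference in GC between them could give such a ratio. GC-dependent recovery, alone or mixed with the number of genes, stays open.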

How the results depend on the processing

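No alternative turned a list called above into one called below, or the reverse. The order of the Hox groups did change: groups 1 to 5 were the highest without replicate 2 (8.33%) and the lowest without replicate 1 (1.30%) and with gene bodies alone (3.46%), and the anterior Hox list went from percentile 5.81 to 75.6 without replicate 2. Of 89 reruns of main values 44 moved and 45 did not. For many values, not moved meant a change smaller than the SD of the 2 replicates. That margin widens as the replicates disagree, so the shifts of Hox groups 1 to 5 with a replicate left out counted as not moved. In 300 reruns of list percentiles 9 were stronger, 9 weaker and 282 unchanged in call, mostly for the 21 lists not called at first. Among called lists, GC matching kept 1, lost 3 and added 3 others, and peaks of −log10 q of at least 3 kept 1 and lost 3.

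The share of replicate 1 peaks found in replicate 2 was 35.3% with an overlap of 1 base, 9.30% with 80% of the peak, 7.20% with peaks of −log10 q of at least 3 (strict peaks) and 38.4% at equal numbers. That of replicate 2 peaks was 86.6%, 63.3%, 94.5% and 62.2%, and 74.9% with folds of at least 3. Strict filtering of both lists left 62915 replicate 1 peaks and 6443 replicate 2 peaks. The 7.20% is thus held down by the few strict peaks of replicate 2 and does not mean that strong replicate 1 peaks were found less often. The rho of the folds was 0.317 with folds of at least 3 and 0.390 by −log10 p. Of strict pooled peaks 97.4% were kept, and 17.1% of strict replicated peaks touched no replicate 2 peak. Peaks in 1 replicate only, by 50% of the peak and at equal numbers, were 76.5% and 43.4% of replicate 1 and 21.1% and 32.3% of replicate 2.

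Promoters within 2.5 kb held 31.1% of peaks, with exons at 2.51% and introns at 42.5%. Promoters held 20.3% of strict peaks, and 12.6% to 17.0% with a replicate left out. Introns held 54.9% in the pooled list, 53.4% of strict peaks, 53.9% of peaks that touch both replicates, and 55.2% to 55.7% with a replicate left out. Coverage at the TSS ran from 4.99% to 8.90% and its downstream maximum from 18.1% to 30.2% with a replicate left out. Their ratio was 3.14 in the pooled list and ran from 3.39 to 3.63.

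With no matching 1 list was above, and with strict peaks 1 was above and 0 below. With GC matching 2 lists were below, epithelium and posterior Hox, while the olfactory and vomeronasal receptors no longer were. Without chromosome X 2 were below, these receptors and posterior Hox. With a replicate left out, where the call rests on the other replicate alone, 3 to 5 were above and 1 to 2 below. Gene bodies alone gave 5.92% for Hox groups 6 to 8 and 6.39% for groups 9 to 13, which ran from 3.41% to 4.46% with a replicate left out. The X ratio was 0.0274 with strict peaks. The longest stretch was 65.0 kb when joined at 3 kb and 10.5 kb when not joined.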

Other observations

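The genes and name prefixes in this part were chosen after their values were seen, and single prefixes had been looked at before all were scanned. By window coverage, counting genes within 100 kb once, the genes with high values included Bahcc1 on chromosome 11, with 38.4% of its window in replicated peaks (36.7% in replicate 1 and 27.2% in replicate 2), Zmiz1 at 37.4%, Pipox at 37.1%, Ahdc1 at 36.0%, Cxxc5 at 35.5%, Tcf20 at 33.7%, Flrt1 at 33.4%, Lyl1 at 32.2% and Map4k4 at 31.3%. Zmiz1, Ahdc1, Cxxc5 and Map4k4 also hold stretches among the 10 longest. Lyl1 lies within the annotated body of Nfix, so its window holds part of that gene.

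Gene names were also grouped by their first 3 letters, with neighbours within 100 kb counted once, which gave 86 prefixes of at least 30 genes and 10 loci. Matched on TSS number, 19 of the 86 prefixes were above random lists and 7 below in the replicated list and both replicates. With GC matching 5 were above and 5 below. Each bound takes 2.5% of random lists in a single list, so an above call with TSS matching was common among name prefixes. Under both matchings 4 prefixes were above and 3 below. Above were Map (73 genes, mostly mitogen-activated protein kinases and microtubule-associated proteins, median 4.85%), Ndu (46 genes, mostly of mitochondrial complex I, 4.71%), Rab (82 genes, mostly small GTPases of membrane traffic, 4.16%) and Ube (42 genes, mostly of the ubiquitin pathway, 4.07%). Below were Krt (113 genes in 14 loci, mostly keratins and keratin-associated proteins, 0.186%), Cld (35 genes, mostly claudins, 0.349%) and Cyp (107 genes, mostly cytochromes P450, 0%). The ribosomal protein prefixes Rpl (5.11%) and Rps (5.22%) were above with TSS matching alone, at percentiles 96.2 and 96.4 with GC matching in the replicated list. Prefixes mix unrelated genes, and no explanation was tested.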
